A study of Rattus norvegicus with 4 samples.

How the data were processed

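Expression was measured in 4 exposed cultures of NR8383 cells, which form 1 group. Per the labels' protocols, cells were grown with 15% serum, seeded 48 h earlier in 25 cm2 flasks and exposed after 20 passages. RNA with a RIN above 7.5 was used, and 100 ng was labelled with Cy3 for 1-colour Agilent arrays. The study's untreated cultures were not analysed here, so no comparison between groups was made. The labels call the cultures biological replicates.

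The deposited files hold spot intensity, per the file headers made with Agilent Feature Extraction 11.0.1.1 and its protocol GE1_1100_Jul11 on array design 074036. The processed intensity is background-subtracted and detrended within the array by the authors' software, with low spots raised to a floor above 0, and was not normalized between arrays, per the file headers. The deposited files also give unsubtracted median intensity of the spot and of its local background, and flags of 0 or 1 for spots well above background, saturated or not uniform. All 4 arrays lay on 1 slide and were scanned once. Each array held 62976 spots, of which 58717 were gene spots and 308 negative controls.

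Control spots were left out. Spots marked as outliers (634, 723, 486 and 644 gene spots on replicates 1 to 4) were left out of the intensity values. They were kept in the calls of signal well above background. No spot was saturated. Spots of a probe were averaged on the log2 scale. The log2 processed intensity of each array was set against its 75th percentile over the probes well above background on all 4 arrays, because under 50% of probes were (22.9%). The plan named each array's 75th percentile, and the set of probes was settled once this share was known. A level is the difference from this reference. The deposited files give accessions and no gene symbols. Probes were named by matching the accession, without version, to a reference gene table of the GRCr8 assembly, used for names only. Of 45598 probes, 21109 (46.3%) matched, giving 16581 genes, and 24489 stayed unnamed. A probe was well above background on an array when more than 50% of its spots were, and a gene when any of its probes was. A gene's level was that of its probe with the highest mean, and in the test between arrays that of its brightest probe among those past the test. Of the genes, 3658 had several probes. Depth on arrays is signal over background: the 99th percentile of negative controls was 5.62, 5.48, 5.07 and 5.96 intensity units on replicates 1 to 4, and the median coefficient of variation of repeated spots was 9.73%, 6.94%, 4.96% and 6.27%. The number of arrays, 4, limits the precision.

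Levels, SDs and detection were described without a test. The 26 gene lists held 422 entries, of which 399 were measured. For each list with at least 5 detected members, the mean deviation of members from their own means was taken per array, and its range over arrays was set against 10000 random lists of the same size matched on mean level. This percentile describes these arrays and is no p-value. Differences between arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, moderated F, Benjamini-Hochberg) on the 1594 probes printed at 2 or more spots and detected on all 4 arrays, with spots as replicates within an array. The spots share 1 culture's RNA, so these p-values concern arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

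Lists, tests, alternatives and the genes to be named were fixed before the data were examined. Named were, for each list, the first 4 detected members and the first 2 not detected on any array; the 20 genes with the highest SD among those past the limma test without a fold minimum; and the 3 detected members with the highest SD in each list above the 95th percentile. Some genes that this rule picks are not reported here. It asked for symbols from the files, and those from the reference table were used in their place. Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of detected probes, the mean over a gene's probes, no filter on dim probes, other detection rules, other fold minima, the median over list members, a block for the top or bottom part of the array, and each replicate left out. The files used here have no mean spot signal, so normexp was run on the median signal. Scaling over all probes and leaving out list members in turn were added after seeing the data.

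The steps were tested on simulated data. The limma test between the 4 arrays was run on 1594 probes by adjusted p alone, without a fold minimum. It called 97 of 100 probes changed by 1 on the log2 scale, 99 of 100 changed by 2, and 0.789% of 1394 unchanged ones. For lists of 15 genes among 5824, 3 of 40 without a shift passed the 95th percentile, and shifts of 0.5 and 0.25 gave percentiles of 100.0 and 99.7. The genes simulated for lists varied independently with 1 common SD, without a trend shared on an array. The list rates therefore do not show how often real lists would pass.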

Results

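Gene expression was measured in NR8383 cells, a line of rat alveolar macrophages started from cells washed out of the lung of a normal rat. Titanium dioxide particles of the NM105 type, a mixture of the crystal forms anatase and rutile also sold as P25, were given at a particle surface of 3 cm2 per cm2 of culture for 4 h. The study set exposed cultures against untreated ones, with 4 biological replicates of each. The 4 exposed cultures (replicates 1 to 4) are described here, and the untreated cultures were not analysed here. No effect of the particles can therefore be tested, and none of the values below is a response to them. What the data give is which named genes gave signal in the exposed cells, how strong it was, and how far the 4 replicates differed. RNA of each culture was labelled with Cy3 and hybridised to 1 array, and all 4 arrays lay on 1 slide. Of 45598 gene probes, 14407 gave signal well above background on the replicate 1 array, 10809 on replicate 2, 12038 on replicate 3 and 11911 on replicate 4. The 75th percentile of signal over the probes detected on all 4 arrays was 1431 intensity units on replicate 1, 585 on replicate 2, 767 on replicate 3 and 831 on replicate 4.

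**Figure D1:**
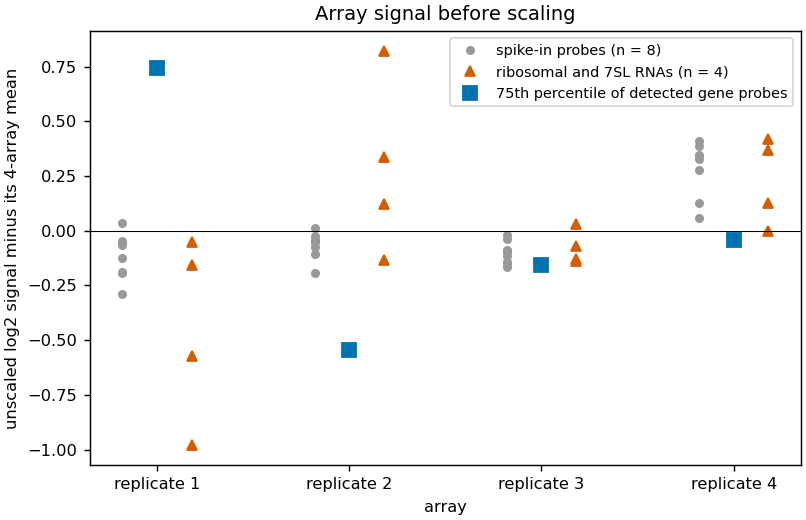
Unscaled log2 signal on each array minus the 4-array mean, for the 75th percentile of detected gene probes (squares), 8 spike-in probes (circles) and 4 ribosomal and 7SL RNAs (triangles). The gene reference lay at 0.74 on replicate 1 and −0.55 on replicate 2, while the spike-in probes averaged −0.12 and −0.07 there.

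The first question was which genes the exposed macrophages expressed. Of 16581 named genes, 5830 (35.2%) were well above background on all 4 arrays and 8896 on none. A further 961 passed on 1 array, 385 on 2 arrays and 509 on 3. Of the genes on 26 lists fixed before the data were examined, genes of housekeeping, the cell cycle, endoplasmic reticulum stress, the lysosome and the antioxidant response gave signal most completely, and no marker of epithelium, fibroblasts or red blood cells was detected on all 4 arrays. Levels below are log2 signal relative to the array's own reference, as mean ± SD over the 4 arrays (n = 4). They place the same gene on different arrays, and levels of different genes are not comparable, since each probe has its own brightness. Detection is Agilent's call for each spot, with no test between genes. A gene given as not detected had no named probe well above background, and may still be expressed. Of 24489 probes without a gene name, 3534 were well above background on all 4 arrays.

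Markers of macrophages were detected in part. Of 20 measured macrophage markers, 15 were well above background on all 4 arrays and 5 on none. Cd68, a lysosomal glycoprotein of macrophages, was at 2.28 ± 0.14. Csf1r, the receptor for macrophage colony-stimulating factor, was at −3.03 ± 0.45, the integrin subunit gene Itgam at −1.59 ± 0.38 and the lipopolysaccharide co-receptor Cd14 at −2.84 ± 0.27. Adgre1, which encodes the F4/80 antigen, and Cd74, the invariant chain of MHC class II, were not well above background on any array. Of 18 measured markers of alveolar macrophages, 13 were detected on all 4 arrays, 1 on some arrays and 4 on none. Pparg, a nuclear receptor needed for alveolar macrophage development, was at 1.68 ± 0.05. The lectin gene Siglec1 was at −2.04 ± 0.32, and the fatty acid binding protein genes Fabp4 and Fabp5 were at −2.62 ± 0.33 and 3.75 ± 0.08. The scavenger receptor gene Marco and the carbonic anhydrase gene Car4 were not well above background on any array.

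Inflammatory signalling genes were partly detected. Of 24 measured cytokine, chemokine and mediator genes, 12 were well above background on all 4 arrays, 3 on some and 9 on none. Il1b was at 1.49 ± 0.28, Tnf at 0.71 ± 0.41, Il1a at −2.44 ± 0.34 and the monocyte chemoattractant gene Ccl2 at 1.98 ± 0.58. Il6 and Ccl20 were not well above background on any array. Among 13 measured targets and parts of the NF-κB pathway, 11 were detected on all 4 arrays and 2 on none. The inhibitor gene Nfkbia was at 0.21 ± 0.31 and its relative Nfkbie at −2.62 ± 0.19. The adhesion molecule gene Icam1 was at −0.19 ± 0.31 and Bcl3 at −2.24 ± 0.25, while Birc3 and Traf1 were not detected on any array. Of 14 measured inflammasome and cell death genes, 7 were detected on all 4 arrays, 4 on some and 3 on none; the count of 7 was 11 when signal above the 99th percentile of the negative controls was asked for instead. The inflammasome sensor gene Nlrp3 was at −4.09 ± 0.52 and its adaptor Pycard at −1.83 ± 0.18. Bax, which promotes cell death, was at 1.39 ± 0.19 and Mcl1, which opposes it, at −1.73 ± 0.14. Bcl2 was not detected on any array. Of 20 measured interferon-response genes, 12 were detected on all 4 arrays, 4 on some and 4 on none. Mx2 was at −0.52 ± 0.34, Isg15 at −3.17 ± 0.20, Oas1a at −2.78 ± 0.16 and the transcription factor gene Irf1 at −0.90 ± 0.15, and Ifit1 and Ifit3 were not detected on any array. Of 17 measured immediate early genes, 9 were detected on all 4 arrays, 3 on some and 5 on none. Jun was at −1.51 ± 0.51, Junb at −4.43 ± 0.16, Ier2 at 0.11 ± 0.21 and Ier3 at −1.39 ± 0.24, with Egr1 and Fosl1 not detected on any array.

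Stress-response genes followed. Of 20 measured genes of the NRF2 antioxidant response, 17 were detected on all 4 arrays, 2 on some and 1, Gclm, on none. The heme oxygenase gene Hmox1 was at 2.03 ± 0.24, Nqo1 at −4.22 ± 0.32, Gclc, the catalytic subunit of glutathione synthesis, at −1.93 ± 0.34 and the sulfiredoxin gene Srxn1 at 0.65 ± 0.25. Of 14 measured metal and iron genes, 8 were detected on all 4 arrays, 1 on some and 5 on none. The metallothionein gene Mt1 was at 0.89 ± 0.29, the zinc exporter gene Slc30a1 at −3.13 ± 0.18, and the ferritin chain genes Fth1 and Ftl1 were at 6.53 ± 0.50 and 7.02 ± 0.40. Mt2A and the iron exporter gene Slc40a1 were not detected on any array. Of 12 measured heat shock genes, 8 were detected on all 4 arrays, 1 on some and 3 on none. The chaperone gene Hspa8 was at 4.87 ± 0.20, Hspb1 at −5.22 ± 0.48, and the mitochondrial chaperonin genes Hspd1 and Hspe1 were at 0.06 ± 0.20 and 1.88 ± 0.23. Hspa1a and Hsph1 were not detected on any array. Of 16 measured genes of endoplasmic reticulum stress, 15 were detected on all 4 arrays and 1 on some. Ddit3, which encodes CHOP, was at −0.62 ± 0.08, Atf4 at 1.52 ± 0.30, the chaperone gene Hspa5 at −0.05 ± 0.06 and Xbp1 at 0.03 ± 0.03. Of 16 measured DNA damage response genes, 7 were detected on all 4 arrays, 6 on some and 3 on none, and 13 were detected on at least 1 array. The cell cycle inhibitor gene Cdkn1a was at 0.42 ± 0.51, Gadd45a at −4.30 ± 0.25 and Bbc3 at −1.42 ± 0.22, while Tp53inp1 and Btg2 were not detected on any array.

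Genes for uptake and digestion of particles were mostly detected. Of 23 measured lysosome and autophagy genes, 20 were detected on all 4 arrays, 2 on some and 1, the cathepsin gene Ctsk, on none. The membrane protein genes Lamp1 and Lamp2 were at −0.49 ± 0.07 and −0.33 ± 0.25, and the cathepsin genes Ctsb and Ctsd at 5.58 ± 0.12 and 5.90 ± 0.13. Of 18 measured uptake receptors and their partners, 11 were detected on all 4 arrays, 2 on some and 5 on none. Cd36 was at −0.04 ± 0.47, Scarb1 at −0.70 ± 0.10, and the Fc receptor genes Fcgr2a and Fcgr3a were at 3.75 ± 0.10 and 0.98 ± 0.08. The scavenger receptor genes Marco and Msr1 were not detected on any array. Of 18 measured genes of matrix remodelling, 7 were detected on all 4 arrays and 11 on none. The elastase gene Mmp12 was at −3.78 ± 0.57, Mmp9 at −1.45 ± 0.23, Timp2 at 4.35 ± 0.04 and Tgfb1 at −0.33 ± 0.20, with Mmp14 and Mmp8 not detected on any array.

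Metabolic and growth genes were detected in large part. All 18 measured cell cycle genes were well above background on all 4 arrays. The proliferation marker gene Mki67 was at −2.90 ± 0.86, the cyclin genes Ccnb1 and Ccna2 at −2.00 ± 0.33 and −1.55 ± 0.37, and the kinase gene Cdk1 at 1.06 ± 0.38. Of 18 measured cholesterol and lipid genes, 13 were detected on all 4 arrays, 3 on some and 2, Scd and Fasn, on none. Hmgcs1 was at −0.94 ± 0.48, Sqle at −1.53 ± 0.37 and Insig1 at −1.27 ± 0.43. Of 17 measured hypoxia and glycolysis genes, 13 were detected on all 4 arrays, 1 on some and 3 on none. The glucose transporter gene Slc2a1 was at 0.21 ± 0.21, Hk2 at −4.02 ± 0.23, Pfkfb3 at −2.40 ± 0.23 and the lactate dehydrogenase gene Ldha at 4.92 ± 0.19, and Vegfa and Car9 were not detected on any array. All 15 measured housekeeping genes were detected on all 4 arrays, with Actb at 5.16 ± 0.28, Gapdh at 6.23 ± 0.41, Hprt1 at −0.77 ± 0.30 and Ppia at 5.35 ± 0.20.

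Markers of other cell types were sparse. None of 12 measured epithelial markers was detected on any array, Epcam and Cdh1 among them, and none of 8 measured red blood cell genes was, Hbb and Hba-a2 among them, although 1 of these 8 lay above the 99th percentile of the negative controls on all 4 arrays. Of 10 measured fibroblast markers, 9 were detected on no array, Col1a2 and Col3a1 among them, and 1 on some. Of 9 measured endothelial markers, 3 were detected on all 4 arrays and 6, with Kdr and Tek, on none. These 3 were Pecam1, which macrophages also express, at −2.52 ± 0.21, Cdh5 at −5.35 ± 0.33 and the von Willebrand factor gene Vwf at 1.02 ± 0.39. Of 10 measured T cell markers, only Cd4, which rat macrophages also express, was detected on all 4 arrays, at −4.25 ± 0.46. One other was detected on some arrays and 8, with Cd3e and Cd3d, on none. Yet 2 of the 10, Cd4 and Cd3d, lay above the 99th percentile of the negative controls on all 4 arrays. Of 8 measured B cell markers, 2 were detected on all 4 arrays and 6, with Cd79b, on none. These 2 were Pax5 at −3.43 ± 0.41 and Fcrla at −0.32 ± 0.11. Of 11 measured neutrophil and mast cell markers, 1, the cathelicidin gene Camp, was detected on all 4 arrays, at −0.20 ± 0.19, 1 on some and 9, with S100a9 and Elane, on none, and 2 of the 11 lay above the 99th percentile of the negative controls on all 4 arrays.

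The next question was how far the 4 arrays, 1 for each exposed culture, differed from each other. Such differences also hold extraction, labelling and hybridisation. Over the 8 spike-in probes well above background on all 4 arrays, the SD of unscaled log2 signal ran from 0.055 to 0.296. The gene SDs below are therefore no measure of culture alone. Over the 5824 named genes with at least 1 probe detected on all 4 arrays, the median SD was 0.225 on the log2 scale, and the 25th and 75th percentiles were 0.156 and 0.319. The SD was above 0.5 for 326 genes, and for 167 after normexp correction. That count was 160 without replicate 1, 402 without replicate 2, 531 without replicate 3 and 528 without replicate 4. Runs with a replicate left out use fewer arrays and their own sets of detected genes, 6255 genes without replicate 2. Between replicates 3 and 4, 20 of these genes differed at least 2-fold, against 326 between replicates 1 and 2. Pearson's correlation across genes, which are not independent replicates, ran from 0.977 for replicates 1 and 2 to 0.993 for replicates 3 and 4. Replicate 1 lay farthest from the gene's mean for 37.3% of genes, replicate 2 for 33.5%, replicate 3 for 16.3% and replicate 4 for 12.9%. Without the filter on dim probes the median SD was 0.464, and it was above 0.5 for 7521 of 16581 genes. That run takes in the 8896 genes detected on no array, which lie near background. After scaling, the median negative control itself lay at −8.67, −7.35, −7.71 and −7.76 on replicates 1 to 4. The scaled background thus adds to these SDs, which are no measure of spread between cultures.

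Single genes were compared between the arrays where a probe was printed at several spots. The proliferation marker gene Mki67 had an SD of 0.86 and was at −1.64 on replicate 1 against −3.55, −3.26 and −3.15 on replicates 2 to 4 (limma moderated F, adjusted p = 2.47e-24). The spindle checkpoint kinase gene Bub1 had an SD of 0.61 and was highest on replicate 1 as well, at −3.14 (limma adjusted p = 0.000692). Ccl2 went the other way, at 1.19 on replicate 1 and 1.91, 2.48 and 2.33 on replicates 2 to 4 (limma adjusted p = 2.60e-17). In all, 39 of 871 genes tested had a limma adjusted p under 0.05 with the highest array at least 2-fold above the lowest. The test sets arrays against the error between spots of 1 probe, whose median SD was 0.098, so it takes differences of culture, extraction, labelling and hybridisation together and shows nothing about the particles. It called 237 genes with a fold minimum of 1.5, 739 with none and 20 after normexp correction. Without the filter on dim probes, where genes near background enter, it called 379. Run without replicate 1 the test called 10 genes, and without replicate 2 it called 22. The SD of Mki67 was 0.50 after normexp correction and 0.21 without replicate 1, that of Bub1 0.17 and 0.29, and that of Ccl2 0.59 and 0.30.

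Of the 20 genes with the highest SD among those past this test without the fold minimum, 19 are given here. Mki67 had an SD of 0.86 and Rpl22l1, a relative of a ribosomal protein gene, 0.85, and Rpl22l1 was above Mki67 under all 4 other scalings or corrections, for instance at 0.86 against 0.80 under quantile scaling. Tpr of the nuclear pore had an SD of 0.67, the calpain inhibitor gene Cast 0.66 at its probe in the test, the chromatin protein gene Dek 0.66, Bub1 0.61, the kinetochore gene Knstrn 0.60, the tetraspanin gene Cd53 0.59, the kinase gene Aak1 0.59, Cops2 of the COP9 signalosome 0.59 and Ccl2 0.58. Man2a1, a mannosidase of the Golgi, had an SD of 0.57, Cacybp 0.54, Ubald1 0.53, the ERK phosphatase gene Dusp6 0.53, Taf9 0.53, Ssb, which encodes the La protein, 0.53, the noncoding gene Gas5 0.52 and Plpp7 0.52. The brightest probe of Cast, printed at 1 spot and so outside the test, had an SD of 0.59 and was highest on replicate 3, at −3.05, and lowest on replicate 4, at −4.31, so the probes of this gene disagree. The limma adjusted p of the 19 genes ran from 2.47e-24 for Mki67 to 0.0165 for Rpl22l1. The SD was over 1.5 times lower for 11 of the 19 genes after normexp correction, where their median SD fell from 0.59 to 0.31, for 12 genes without replicate 1 and for 3 without replicate 2. The genes lower after normexp were Mki67, Tpr, Cast, Dek, Bub1, Knstrn, Cops2, Man2a1, Cacybp, Taf9 and Ssb. That alternative starts from the unsubtracted median signal and adds an offset of 50, so it changes more than the background. Adding an offset shrinks log2 differences most where signal is low, and these 11 genes were dim, with mean levels from −3.98 to −2.30. Of the other genes, Aak1 was dim too, at −4.33, with an SD of 0.51 after normexp, and the rest lay at −1.45 or above. The share of the offset in the lower SDs was not tested. Of these 19 genes, 10 were highest on replicate 1 and 12 were lowest on replicate 2, while none was lowest on replicate 4. Replicate 1 was also the array with the highest gene signal and replicate 2 the one with the lowest.

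**Figure D2:**
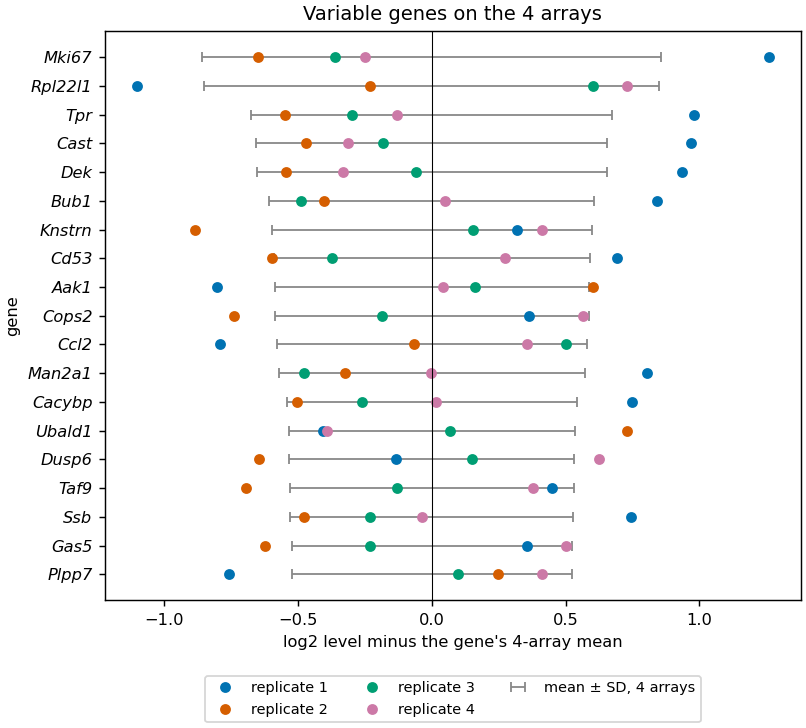
Log2 level of each of these 19 variable genes on the 4 arrays (points, coloured by replicate) minus the gene's mean over the 4 arrays, with bars of 1 SD to each side (n = 4). Mki67 and Rpl22l1 have SDs of 0.86 and 0.85, in an order that turned under the 4 other scalings or corrections, the SD of 11 of the 19 genes was over 1.5 times lower after normexp correction, and 10 of the 19 genes have their highest point on replicate 1, of which 9 did so under quantile scaling, under scaling to the median and under scaling over all probes, and 10 under normexp correction.

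Gene lists were then compared between the arrays, to see whether genes of a pathway moved together. Of 19 lists with at least 5 detected members, 5 had a range between arrays above the 95th percentile of random lists of the same size and level. Of 19 lists of genes drawn at random, 0.95 would pass by chance. Lists of genes that vary together for any reason would pass more often. The cell cycle list was highest on replicate 1 and lowest on replicate 2, with mean deviations of 0.20 and −0.21 over 18 genes, a range of 1.33-fold at percentile 99.9. On replicate 1, 13 of the 18 genes lay above their own mean, against 4 on replicate 2. Mki67, Bub1 and the kinase gene Aurkb had the highest SD, the last at 0.50, but after normexp correction Bub1 was at 0.17 and Aurkb at 0.12, below Cdk1 at 0.40. The percentile was 38.5 after normexp correction, 74.7 with scaling over all probes and 93.7 without replicate 2, and under normexp the sign on replicate 3 turned and replicate 4, at 0.04, lay above replicate 1, at 0.02.

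The cytokine and chemokine list was lowest on replicate 2 and highest on replicate 4, at −0.19 and 0.21 over 12 genes, a range of 1.32-fold at percentile 99.6. Its signs held and replicate 4 was highest under the 4 other scalings or corrections. But replicate 1 was the lowest in place of replicate 2 after normexp correction (−0.17 against −0.13), with scaling to the median (−0.19 against −0.14) and with scaling over all probes (−0.21 against −0.10). On replicate 4, 11 of 12 genes lay above their own mean, against 3 on replicate 2. Ccl2, the inflammasome-processed cytokine gene Il18 and the chemokine gene Ccl9 had the highest SD, the last 2 at 0.51 and 0.47. All 3 were lowest on replicate 1, without which their SDs were 0.30, 0.10 and 0.30. After normexp correction Ccl9, at 0.41, was below Tnf, at 0.44. Without the filter on dim probes the list's percentile was 85.8.

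The other lists that passed, 3 in number, were highest on replicate 1 in the reference scaling. That array had the highest gene signal, and its dimmest 25% of genes lay at a median of 0.12 above their means. The NF-κB list was at 0.26 on replicate 1 and −0.17 on replicate 3 over 11 genes (percentile 98.8), with 10 of 11 genes above their own mean on replicate 1. Tnfaip2, Nfkb1 and Nfkbia had its highest SD, at 0.44, 0.41 and 0.31, but after normexp correction Nfkb1 was at 0.08 and Nfkbia at 0.07, below Icam1 at 0.34. The list fell to percentile 77.1 without replicate 1, 93.0 after normexp correction and 23.1 without the filter on dim probes. Its sign on replicate 4, near 0, turned under all 4 other scalings or corrections. The uptake receptor list was at 0.19 on replicate 1 and −0.14 on replicate 2 over 11 genes (percentile 98.8). The signs held under the 4 other scalings or corrections, although replicate 3 was the lowest under quantile scaling and with scaling over all probes. Cd36, the integrin gene Itgb1 and the glucan receptor gene Clec7a had its highest SD, at 0.47, 0.33 and 0.31, and Itgb1 was at 0.25 after normexp correction, the fifth of the 11 members. Its percentile was 28.8 with scaling over all probes, 57.0 with scaling to the median, 93.1 with the mean over probes, 81.9 with the median over members and 81.9 without replicate 1, and 0.32 without the filter on dim probes. The macrophage list was at 0.16 on replicate 1 and −0.11 on replicate 3 over 15 genes (percentile 96.8). Its signs on replicates 2 and 4 turned under other scalings or corrections. It was highest on replicate 4 after normexp correction and on replicate 2 with scaling over all probes. Aif1 and the leukocyte antigen gene Ptprc were among the members with its highest SD, at 0.50 and 0.49, and Ptprc was at 0.23 after normexp correction, below Itgam at 0.57. Its percentile was 42.5 without replicate 1, 88.7 without replicate 3, 19.1 after normexp correction, 35.0 with scaling over all probes, 51.5 with scaling to the median, 35.6 without the filter, 92.2 with the mean over probes and 90.2 with the median over members.

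The other 14 lists stayed at or below the 95th percentile. The metal and iron list was at percentile 86.5, and it passed at 97.4 after normexp correction, 95.2 with the median over members and 96.6 without replicate 1. The antioxidant list was at percentile 78.1, the interferon list at 72.7, the inflammasome and cell death list at 65.9, the DNA damage list at 65.0 and the alveolar macrophage list at 54.5. The lysosome list was at percentile 38.0, the heat shock list at 28.4, the cholesterol list at 28.4, the hypoxia list at 21.7, the matrix list at 18.8, the immediate early list at 17.6, the housekeeping list at 12.5 and the endoplasmic reticulum stress list at 10.3.

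**Figure D3:**
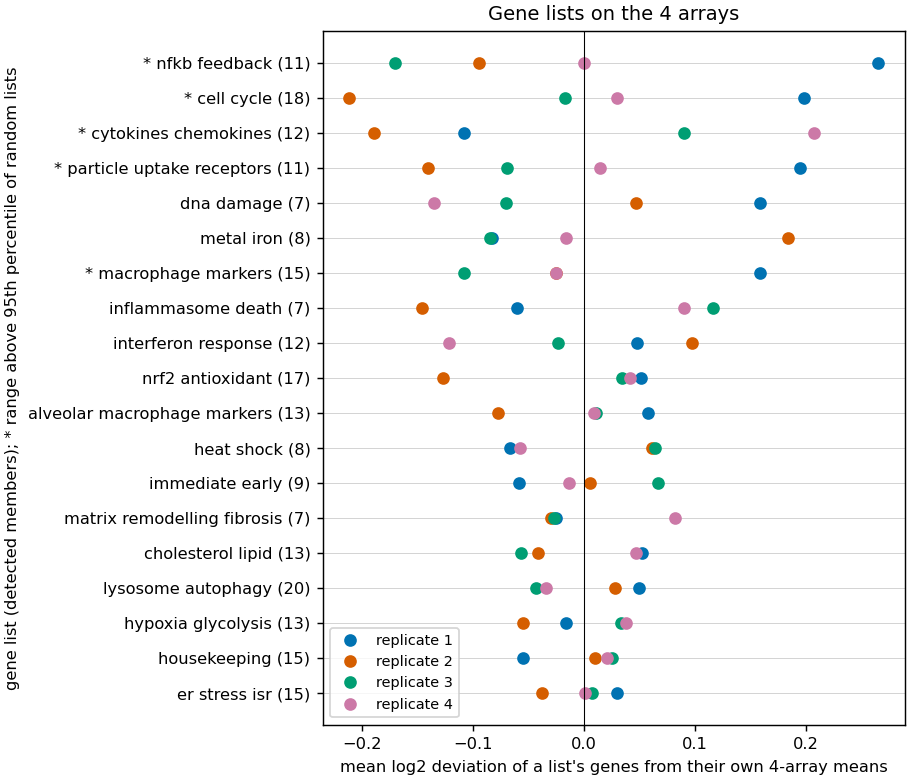
Mean log2 deviation of each list's detected genes from their own means over the 4 arrays, by replicate (points), for the 19 lists with at least 5 detected members, whose number stands in parentheses, and with a star on the 5 above the 95th percentile of random lists. In the reference scaling, which is the one shown, the NF-κB list has the widest spread, from −0.17 on replicate 3 to 0.26 on replicate 1. Its sign on replicate 4 turned under all 4 other scalings or corrections.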

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

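The tests on array signal and on scaling were chosen after the results were seen; those that leave out list members or use second probes were added after the data were examined, with the outcome each explanation needs written before their results were seen. No biological explanation was tested, since the 4 cultures form 1 group.

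Gene signal on the replicate 1 array lay above that on replicate 2 by 1.29 on the log2 scale. Spike-in RNA did not follow: the mean difference of 8 spike-in probes was −0.0484 (SE 0.0512), which argues against brightness of the whole array. Ribosomal and 7SL RNAs, unscaled, differed by −0.727 (SE 0.408, n = 4), from −1.80 for Rn5-8s to −0.02 for Rn7sl1. This argues against more total RNA in the reaction only if their signal follows the RNA put in, which was not tested. Of these 4 genes, 3 belong to ribosomal RNA and are not independent. Relative to the gene reference these RNAs differed by −2.02, so a larger share of messenger RNA among the labelled RNA on replicate 1 may explain the gap. That last value holds the 1.29 itself, so it leans on the pattern it tests.

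The cytokine and chemokine list differed between arrays at percentile 99.6. Under 4 other scalings or corrections its lowest percentile was 97.35, and with any 1 of its 12 members left out the lowest was 98.63. A single member thus does not account for it. That the list passed did not hang on the scaling or correction, but which array was lowest did. Without the filter on dim probes it did not pass. Differences between cultures, extraction and labelling cannot be separated, as each culture had 1 array, and stay open.

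The cell cycle list differed at percentile 99.9. Its range was 0.41 with the reference scaling and 0.10 after normexp correction, where the percentile fell to 38.51, while it stayed above 95 under 2 of 4 other scalings or corrections, so scaling could be part of it and cannot be told apart from a difference between cultures. A single member does not account for it, since the lowest percentile with 1 of 18 left out was 98.78. Second probes, for 4 genes, gave a mean difference of 0.5837 (SE 0.526) between replicates 1 and 2, against 0.68 for their first probes. Mki67 carried this mean, at 2.16 on its second probe and 1.91 on its first. The second probes of Mcm2, Mcm4 and Rrm2 were at −0.01, 0.11 and 0.07, against 0.04, 0.42 and 0.36 for their first probes. The mean met the prediction written beforehand for single probes, a value within 2 SE of 0. The first-probe difference lies within 2 SE as well. That further condition was added after the value was seen, and with 4 genes the question stays open.

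Of 141 values tested for 1 array far from the other 3, 6 passed Dixon's limit, where 7.1 would by chance. The antioxidant list was low on replicate 2 (gap over range 0.904) and the matrix list high on replicate 4 (0.960). Il1a was low on replicate 2 (0.923) and Mt1 high there (0.844). Gadd45a was high on replicate 1 (0.837) and Il18 low there (0.831).

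Among data outside the comparisons, the control probe ERCC-00148_99 had a mean log2 signal of 6.09, the 1 of 96 ERCC probes well above background on all 4 arrays. Of 24489 probes without a gene name, 3534 (14.4%) were well above background on all 4 arrays, against 32.7% of named ones.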

How the results depend on the processing

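The plan named each array's 75th percentile; taking it over detected probes was settled once detection was known, and scaling over all probes was added after seeing the data. No paired analysis was possible because all 4 samples form 1 group, and a slide block was not run because all arrays lay on 1 slide. The 5830 detected genes stayed within 1.5 times under every detection rule and left-out replicate run (5838 to 7685), as did the 238 detected list members (238 to 275). The median SD of 0.225 stayed between 0.183 and 0.239 except without the filter on dim probes, at 0.464, where genes near background enter. Against 5 lists above the 95th percentile, 3 passed after normexp correction, 3 with scaling to the median, 2 with scaling over all probes, 3 with the mean over probes and 1 without the filter, and 3 to 5 with a replicate left out (3 without replicate 1). Against 39 genes that differed between arrays, a fold minimum of 1.5 gave 237, no minimum 739, normexp 20 and no filter 379; leaving out a replicate gave 10 (without replicate 1) to 37, with 22 without replicate 2. Apart from the filter and the fold minimum, the cause was not tested. Normexp moved all detected probes on replicate 1 by a median of −0.11, and scaling over all probes by −0.10. Of 1110 alternative levels of 111 genes picked by the naming rule, 107 moved by over 1 SD, 48 of them under normexp. Low signal on replicate 2, with the 99th percentile of negative controls at −6.74 against −7.99 on replicate 1, limits which dim genes count as detected.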

Other observations

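Gene families outside the lists were chosen after seeing the data. Of 95 cytosolic ribosomal protein genes, 85 were well above background on all 4 arrays, as were 63 of 68 mitochondrial ribosomal protein genes, 37 of 39 proteasome subunit genes, 81 of 89 genes of the respiratory chain and ATP synthase and 13 of 21 genes of the vacuolar ATPase, which acidifies lysosomes. Of 1161 olfactory receptor genes, 8 (0.689%) were, as were 11 of 122 vomeronasal receptor genes, 0 of 36 taste receptor genes, 2 of 47 keratin genes and 1 of 23 collagen genes. The respiratory chain family differed between arrays at percentile 99.7 of random lists and 95.5 after quantile normalization, and the cytosolic ribosomal family at 96.8 and 99.5, while the ranges themselves fell from 0.25 to 0.16 and from 0.33 to 0.16 on the log2 scale. Proteasome subunits were at 99.3 and mitochondrial ribosomal proteins at 98.3, but at 31.0 and 21.6 after quantile normalization. The 8 olfactory receptor genes were at percentile 100.0 under both, with ranges of 0.86 and 1.07. In the reference scaling they were lowest on replicate 1, at −0.51, and highest on replicate 2, at 0.35. Gene signal before scaling went the other way on these arrays, at 0.74 and −0.55. The reference taken off replicate 1 was 1.29 above that taken off replicate 2, more than the range of 0.86. Before scaling these olfactory receptor genes were therefore higher on replicate 1 than on replicate 2. Their order on these arrays in the reference scaling came from that subtraction. Why they differed less before scaling than the gene reference was not tested. The vacuolar ATPase family was at 84.2 and 64.9 and the vomeronasal receptors at 79.1 and 68.1. The percentile was computed for these 7 families, those with at least 5 detected members.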
